A study of Homo sapiens with 34 samples.

How the data were processed

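Single-cell RNA sequencing was carried out on human ileal mucosa, the lining of the last part of the small intestine, in a study of small intestine neuroendocrine tumours. Per the labels' protocols, mucosa was minced and digested with TrypLE, and live DAPI-negative cells carrying the epithelial surface protein EpCAM were collected by flow sorting before capture with the Chromium 3' v3 kit and Illumina sequencing. The labels place the 34 libraries in 3 groups: 9 of control mucosa (CM), 9 of patient mucosa (PM) and 16 of patient tumour mucosa (PTM). Replicate numbers follow the order of the samples within a group and pair nothing. The labels tie no library to a donor, so p-values measure the spread between libraries, some of which may share a specimen or a donor and so differ only technically.

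The deposited files hold, for each library, raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, in matrices named as filtered. Per the submitters' processing notes, the authors used Cell Ranger 3.1.1 and the GRCh38 (hg38) build; the annotation release is not given in the sources used here. The counts are whole numbers with no normalisation. Gene coordinates, chromosomes and gene types were taken from a GENCODE annotation of GRCh38 by gene identifier, and 33456 of 33538 identifiers matched. XIST, TSIX, Y-linked genes and the variable, diversity and joining segments of immunoglobulins and T cell receptors, 719 genes in all, were left out of every test. Reads shared by near-identical copies were assigned by the authors' counting, so MBD3L2 with MBD3L2B, the metallothioneins and HSPA1A with HSPA1B are uncertain as single genes.

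The files hold 139716 barcodes, 306 to 9788 per library, and 1565136 to 59944543 UMIs per library. Cells with at least 500 genes, at least 1000 UMIs and at most 25% of UMIs from mitochondrial genes were used. Doublets were predicted within each library from 2 simulated doublets per cell (1500 variable genes, 30 principal components), and the highest-scoring cells were removed at a rate of 0.8% per 1000 cells. This left 86957 cells. They were clustered together with the Leiden algorithm at a resolution of 1 (leidenalg 0.10.2, igraph 0.11.9) on 2500 variable genes, 40 principal components and 20 nearest neighbours, with no batch integration, which gave 41 clusters. Clusters were named from markers of 18 cell types. The names read X-like are rebuilt here and can differ from the authors' own. Clusters led by genes against any name, or resting on few markers, stayed unnamed and held 7.03% of CM, 3.35% of PM and 3.48% of PTM cells.

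Counts were summed per sample and class, with at least 10 cells per sample. Each class was fitted once over all 3 groups with the quasi-likelihood test of edgeR 4.0.16 (TMM normalisation, filterByExpr, two-sided, Benjamini-Hochberg adjustment over all genes of the class, threshold 0.05) under R 4.3.3, with no covariates. Log2 fold changes are given with standard errors (SE). Mean counts scaled by library size and TMM factor (CPM) are given with standard deviations (SD). The chromosome scores and cluster values use CPM scaled by library size alone. So do the CPM of CHGA, CHGB, TPH1 and TAC1 in enterocyte-like cells. Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. Shares are of epithelial-class cells in samples with at least 100 of them, compared by two-sided exact permutation of the group means and adjusted over 24 tests. For each autosome, the mean log2(CPM + 1) of genes with a mean of at least 10 CPM, less that of all autosomal genes, was compared between groups by exact permutation. Correlations used 100000 permutations. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used otherwise.

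The groups, classes' markers, 47 gene lists, tests, filters and the rule for named genes were set before the data were examined. By that rule, the text names up to 10 genes with the largest increase and 10 with the largest decrease among those past the threshold with an absolute log2 fold change of at least 1, a mean of at least 20 CPM in the higher group and at least 75% of its samples above the median of the lower group. It also names up to 4 members with the smallest adjusted p of each list described and, in neuroendocrine-like cells, CHGA, CHGB, TPH1, TAC1, SSTR2, CDKN1B and MKI67. MKI67 was too low to be tested there. For privacy, genes whose level in 1 library could reflect a person's genotype or sex were passed over in this choice, which the rule had not foreseen. A fold against a group with 0 counts is a lower bound against 3 counts over the whole group, and with 1 to 3 counts a ratio with a 95% counting interval is given; both cover counting error only.

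PTM replicates 13 and 14 differed by no more than the largest of 100 random reassignments of their cells in both classes that could be compared (0.0696 against 0.0768, mean 0.0578, in enterocyte-like cells), and were counted as 1 sample. That rule was set after the distances between libraries had been seen. A further 5 pairs differed by under 2 times the mean reassignment and were kept apart, and summing all 6 pairs was an alternative. For 1 of these, PM replicates 5 and 6, the rule turned on the random draws: they missed it by 0.0788 against 0.0785 and met it with 17 of 20 other draws (PTM replicates 13 and 14 with 19 of 20). Keeping them apart is thus the rarer outcome. This was found late, the main analysis was left as it was, and summing them as well (2 pairs summed) was an alternative. Libraries that shared far more barcodes than chance gives were taken as sequenced together, which put 9 libraries in set 1, 6 in set 2 and 8 in none, and fits with the set as a term were made in sets 1 and 2. Libraries with under 1000 kept cells, and PTM replicate 4, of whose cells 30.0% had more UMIs under the same barcode in another library, were left out in another alternative. These choices were made after seeing the data. DESeq2 1.42.0, RLE normalisation, no filter on low genes, at least 30 cells, mitochondrial limits of 15% and 50%, predicted doublets kept, a resolution of 2 (59 clusters), fits of 2 groups at a time, the mitochondrial share as a covariate and each library left out in turn were also run. Goblet-, tuft-, BEST4-, Paneth- and other enteroendocrine-like cells were compared by share only, and non-epithelial cells were not compared.

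The steps were tested on simulated counts with 200 changed genes. At an absolute log2 fold change of 1, 40% of changed genes were recovered in neuroendocrine-like cells for PM against CM, 64% for PTM against CM and 63% for PTM against PM. For the same comparisons the recovery was 78%, 83% and 73% in progenitor-like and 64%, 80% and 76% in enterocyte-like cells. At an absolute log2 fold change of 2 it was 88% or more in each of these 9 tests. A lowering of chromosome 5 by 0.5 was estimated as -0.48, and 4 other autosomes were called with it, since the scores are centred on all autosomes.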

Results

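Gene expression was measured in single EpCAM-sorted cells of the ileum to ask, as the series title puts it in substance, from which cell small intestine neuroendocrine tumours arise and how expression moves in early tumour growth. The comparisons set control mucosa (CM, 9 libraries), patient mucosa (PM, 9) and patient tumour mucosa (PTM, 16) against each other. Depth ranged from 13307624 to 59944543 UMIs per library in CM, from 1565136 to 42160343 in PM and from 2375714 to 47879494 in PTM. After filtering, 35011 CM, 22607 PM and 29339 PTM cells were used, with a median of 4199 to 10906 UMIs per cell in CM libraries, 1889 to 6556 in PM and 2985 to 11006 in PTM. Enterocyte-like cells were the most numerous class (46725), followed by goblet-like (14329), progenitor-like (7827, joining stem and cycling markers), neuroendocrine-like (7148), other enteroendocrine-like (1553), BEST4-like (1452), tuft-like (839) and Paneth-like cells (585). PTM replicates 13 and 14 were counted as 1 sample. PM replicates 5 and 6 were kept apart, though the rule for pairs joined them with 17 of 20 other draws.

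Neuroendocrine-like cells, marked by the granule protein gene CHGA and by TPH1, which encodes the rate-limiting enzyme of serotonin synthesis, made up 23.4% ± 19.5 (SD, n = 14) of epithelial cells in PTM, against 2.45% ± 1.94 (n = 9) in CM and 5.09% ± 3.60 (n = 9) in PM. The differences in means of 20.98 percentage points from CM and 18.33 from PM passed the exact permutation test (adjusted p = 0.0335 for both). The SD of 19.5 points between PTM samples was of about the same size. The difference between PM and CM did not pass (adjusted p = 0.159, exact permutation test). PTM samples ranged from 2.74% to 65.3%. Goblet-like cells, the mucus producers, had a share of 9.79% ± 10.1 in PTM (n = 14), 24.8% ± 11.6 in CM (n = 9) and 28.6% ± 21.2 in PM (n = 9). It was lower in PTM against each (adjusted p = 0.0335, exact permutation test). Paneth-like cells were at 0.315% ± 0.358 in PTM and 1.46% ± 1.75 in CM (adjusted p = 0.0335, exact permutation test). Tuft-like cells were higher in PM, at 3.08% ± 2.55, than in CM, at 0.629% ± 0.922 (adjusted p = 0.0335, exact permutation test). Other enteroendocrine-like cells were lower in PTM, at 1.11% ± 1.32, than in PM, at 3.76% ± 2.91 (adjusted p = 0.0335, exact permutation test). The tuft difference of 2.4536 points in PM against CM was 1.1981 with a 15% mitochondrial limit (adjusted p = 0.186, exact permutation) and 1.1437 without doubtful libraries (adjusted p = 0.208, exact permutation). It did not pass with close pairs summed (adjusted p = 0.0559), nor without CM replicates 1, 2, 3, 4, 7 or 8 or PM replicates 3, 7 or 8 (adjusted p = 0.0527 to 0.065, exact permutation in each). The Paneth difference of -1.1462 points rests on CM replicates 4 and 3, at 5.258% and 3.219%, and the medians were 0.3695% in CM and 0.2085% in PTM. It was -0.67163 without CM replicate 4 (adjusted p = 0.0895) and -0.92643 without CM replicate 3 (adjusted p = 0.0857, exact permutation in each). The call was also lost without CM replicates 1 or 2 or PM replicates 3 or 7, and with limits of 15% or 50%, mean logit shares or close pairs summed (adjusted p = 0.0552 to 0.0778, exact permutation). The goblet call against CM was lost with the 15% limit (adjusted p = 0.0726) and without PM replicate 3 or CM replicate 4 (adjusted p = 0.0501 and 0.0515, exact permutation in each). Against PM it was lost with the 15% limit, with close pairs summed, without doubtful libraries, and without PM replicates 1, 2, 3 or 7 or CM replicate 4 (adjusted p = 0.0512 to 0.0919, exact permutation). The call of other enteroendocrine-like cells was lost with the 15% limit, with close pairs summed, and without PM replicate 3 or CM replicate 4 (adjusted p = 0.0512 to 0.0778, exact permutation). Progenitor-like shares were 14.2% ± 11.5, 7.41% ± 3.34 and 9.19% ± 5.35 in CM, PM and PTM. Enterocyte-like shares were 53.3% ± 22.3, 49.7% ± 25.7 and 50.7% ± 19.7. Neither passed the exact permutation test, nor did BEST4-like shares of 1.26% ± 0.986, 1.745% ± 0.975 and 3.51% ± 2.80 (adjusted p = 0.075 for PTM against CM, exact permutation). The BEST4-like share passed without PTM replicates 1, 3 or 6 or CM replicate 9 (adjusted p = 0.0393 to 0.049, exact permutation). The EpCAM sort and the piece of tissue taken set these shares as well as the mucosa itself. Within sequencing sets 1 and 2, the neuroendocrine-like share was 15.48 points higher in PTM than in CM, and each PTM share lay above each CM share of its set. That is the largest increase that any of the 60 splits can give, but it did not pass (adjusted p = 0.1, exact permutation). With so few splits this test decides little either way. Against PM it was 11.96 points higher (adjusted p = 0.168, exact permutation). Both calls were lost with a 15% mitochondrial limit (adjusted p = 0.0629 and 0.0778 against CM and PM, exact permutation) and with close pairs summed (adjusted p = 0.0557 for both, exact permutation). The call against PM was also lost with a 50% limit (adjusted p = 0.073) and without doubtful libraries (adjusted p = 0.0919, exact permutation in each). The call against CM was lost without PM replicate 3 (adjusted p = 0.0501) or CM replicate 4 (adjusted p = 0.0512, exact permutation in each). The call against PM was lost without PM replicates 1, 3, 7, 8 or 9 or CM replicate 4 (adjusted p = 0.0512 to 0.065, exact permutation).

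**Figure D1:**
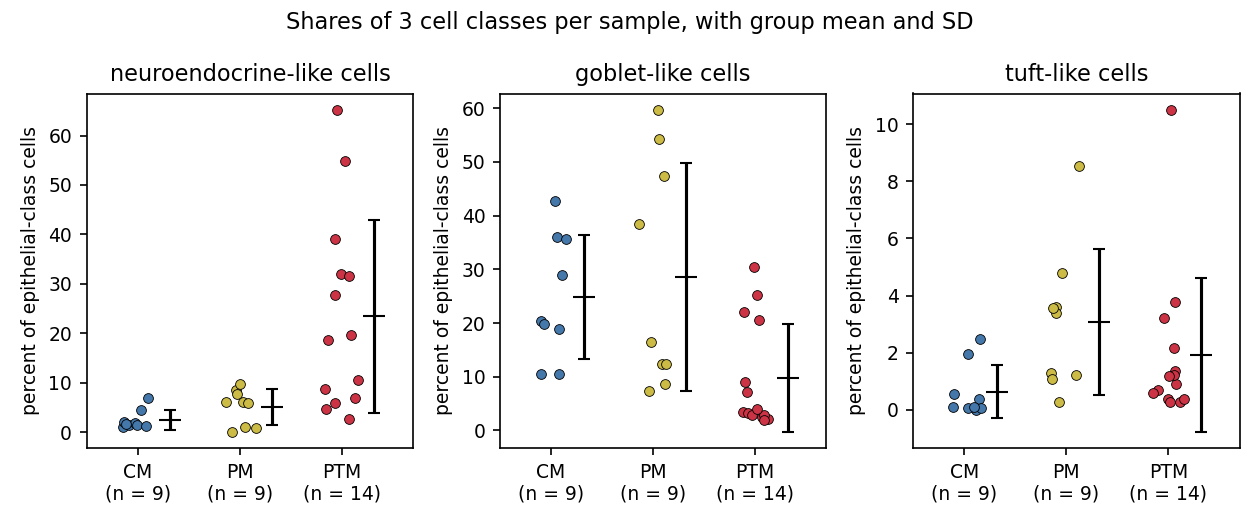
Share of neuroendocrine-, goblet- and tuft-like cells among epithelial-class cells (percent, y axis) in CM (n = 9), PM (n = 9) and PTM (n = 14); each point is a sample, and bars give the mean and SD. Neuroendocrine-like shares lie between 1.09% and 6.84% in CM and between 2.74% and 65.3% in PTM.

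In neuroendocrine-like cells, PM and CM differed at 46 of 9721 genes, a number that depended on the fit. KIF1A, a neuronal motor protein that carries vesicle precursors (chromosome 2, 240713761 to 240821036, GRCh38), rose in PM to 188 ± 49.9 CPM (SD, n = 7) from 58.5 ± 26.96 in CM (n = 8), a log2 fold change of 1.68 ± 0.23 (SE, adjusted p = 0.000281). It was above the CM median in 7 of 7 samples. SNTG1 (chromosome 8, 49909789 to 50796691) rose by 3.52 ± 0.62 (adjusted p = 0.005). AMN, which takes part in vitamin B12 uptake, rose by 2.18 ± 0.42 (adjusted p = 0.0111), both in 7 of 7 samples. C21orf58 also rose. IFI27, an interferon-induced gene (chromosome 14, 94104836 to 94116698), fell to 22.3 ± 17.1 CPM from 186 ± 123, a log2 fold change of -3.01 ± 0.49 (adjusted p = 0.00182, 8 of 8 CM samples above the PM median). CASD1 fell as well. KIF1A, SNTG1, AMN, IFI27, C21orf58 and CASD1 kept their calls when any 1 library was left out and with PM replicates 5 and 6 summed.

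Of 11 heat shock genes, 2 fell in PM, and 8 when adjusted over the list alone. The list as a whole was lower (camera, adjusted p = 1.89e-07, and adjusted p = 0.437 with an estimated correlation). Of 6 goblet cell markers, 2 fell, and 4 when adjusted over the list alone. Summing PM replicates 5 and 6 ended the calls of these 2 and 2 genes, as did leaving out 1 of 15 libraries in 7 to 13 fits each (adjusted p up to 0.127, without PM replicate 4). These markers had camera adjusted p = 0.00191, and adjusted p = 0.478 with an estimated correlation. The class markers CHGA (-0.05 ± 0.22, adjusted p = 0.982), CHGB (-0.43 ± 0.26, adjusted p = 0.548) and TPH1 (-0.31 ± 0.24, adjusted p = 0.677) did not pass the test. Nor did TAC1 (-0.43 ± 1.09, adjusted p = 0.946), SSTR2 (0.64 ± 0.30, adjusted p = 0.413) or CDKN1B (-0.33 ± 0.21, adjusted p = 0.592). The value of TAC1 rests on single libraries: it was -4.326 without PM replicate 9 (adjusted p = 0.0637) and 2.114 without CM replicate 2 (adjusted p = 0.439). With the set as a term TAC1 fell (-5.729, adjusted p = 0.0276). Over 9721 genes, 21 rose and 25 fell (1086 at an unadjusted p under 0.05). In all, 7 of 36 lists passed, 0 with an estimated correlation. Cluster 17 held most of the class in both groups, 626 of 687 CM and 1091 of 1163 PM cells.

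The count of 46 was 10 with PM replicates 5 and 6 summed, 9 with the set as a term and 6 with close pairs summed. It was 218 of 6205 when the 2 groups were fitted alone, with 30 genes shared, and 251 of 6018 in the cells of clusters 17 and 40 alone. Leaving out 1 library gave 10, 11, 13 and 27 without PM replicates 6, 5, 4 and 3. It gave 12, 13, 14, 16, 19 and 28 without CM replicates 5, 7, 8, 6, 4 and 9 in that order, and 54 without PM replicate 1.

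In PTM, neuroendocrine-like cells differed from those of CM at 4365 of 9721 genes, of which 2313 rose and 2052 fell. TAC1, which encodes the precursor of substance P (chromosome 7, 97731908 to 97740472), rose to 2548 ± 1381 CPM (SD, n = 14) from 141 ± 347 (n = 8), a log2 fold change of 4.22 ± 1.08 (SE, adjusted p = 0.00175). SSTR2, the somatostatin receptor targeted in imaging and treatment of these tumours (chromosome 17, 73165012 to 73176633), rose to 98.3 ± 36.2 CPM from 26.7 ± 7.59 (1.89 ± 0.26, adjusted p = 6.62e-07). Both genes lay above the CM median in 14 of 14 samples. Most of the CM level of TAC1 comes from CM replicate 2 (996.8 CPM), and without it the log2 fold change was 6.761 (adjusted p = 1.33e-05). CHGA (chromosome 14, 92923080 to 92935293) fell to 23940 ± 6472 CPM from 52940 ± 8847 (-1.15 ± 0.18, adjusted p = 6.08e-06). CHGB (0.32 ± 0.22, adjusted p = 0.252), TPH1 (-0.47 ± 0.21, adjusted p = 0.0621) and CDKN1B, a cell cycle inhibitor (0.12 ± 0.18, adjusted p = 0.624), did not pass the test. TPH1 passed as lower without PTM replicates 8 or 13 or CM replicates 5, 7 or 8 (-0.5254, -0.5027, -0.5242, -0.5428 and -0.5343).

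The genes with the largest increase had 0 counts in all 8 CM samples. PEG3, an imprinted zinc finger gene (chromosome 19, 56810077 to 56840728), was at least 555-fold higher in PTM (458 ± 289 CPM), UCHL1, a ubiquitin hydrolase of neurons and endocrine cells (chromosome 4, 41256413 to 41268455), at least 260-fold. The lower bound was 233-fold for RGS5, a regulator of G protein signalling (chromosome 1, 163111121 to 163321791), and 173 for RESP18. It was 196 for TCEAL2, 191 for PARVB, 182 for the kinase gene PAK3 and 136 for the glycine receptor subunit gene GLRA3. MBD3L2 (202) and MBD3L2B (117) are uncertain as single genes. These were above the CM median in 14 of 14 PTM samples, PARVB in 13. The largest decreases were in the homeobox gene HOXB5 (-7.75 ± 0.70; chromosome 17, 48591257 to 48593961), SLITRK2 (-7.50 ± 0.71), ZBBX, HOXB3 (-6.81 ± 0.70), PDGFD, HOXB6 (-6.66 ± 0.78), SLC26A7, CEACAM6 (-6.10 ± 0.75), HOXB8 and EPHB6, with 8 of 8 CM samples above the PTM median for each. HOX genes were also lower in PM than in CM in the other classes, so position along the intestine stays open for them. Without PTM replicate 1 most decreases were larger, the most for HOXB8 (-8.169 from -6.0).

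**Figure D2:**
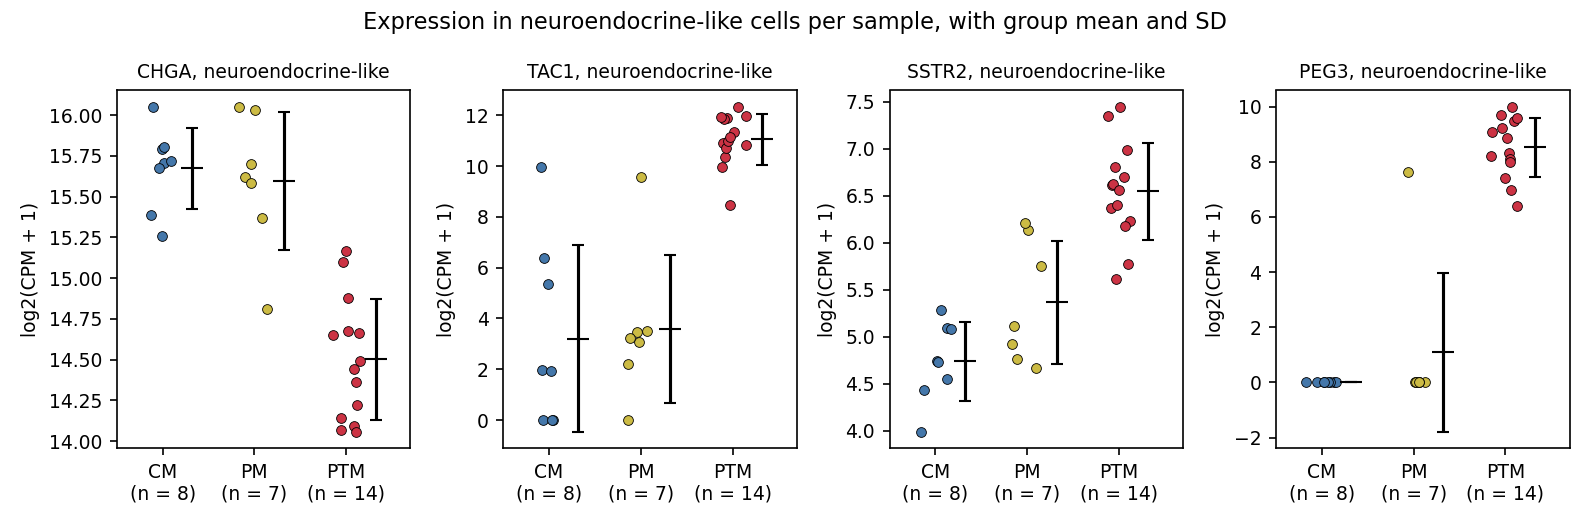
Level of CHGA, TAC1, SSTR2 and PEG3 in neuroendocrine-like cells (log2(CPM + 1), y axis) in CM (n = 8), PM (n = 7) and PTM (n = 14); each point is a sample, and bars give the mean and SD. PEG3 had 0 counts in every CM sample and a mean of 458 CPM in PTM, while CHGA fell from 52940 to 23940 CPM.

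Among genes associated with neuroendocrine tumours, 7 of 10 rose and 1 fell in PTM against CM, the same numbers when adjusted over the list alone. The list had camera adjusted p = 9.72e-05, and adjusted p = 0.0975 with an estimated correlation. They included the cadherin gene CDH6 (4.44 ± 0.46), the receptor tyrosine kinase gene RET (3.61 ± 0.39), PNMA2 (2.97 ± 0.31) and the glutamate receptor subunit gene GRIA2, with a ratio of 659 (95% counting interval 118 to 26000). Of 25 secretory granule genes 10 rose and 3 fell, and 11 and 3 when adjusted over the list alone (camera, adjusted p = 0.0343, and adjusted p = 0.257 with an estimated correlation). PTPRN (6.19 ± 0.65), VAMP2 (1.26 ± 0.17) and RAB3B (1.55 ± 0.21) rose, and SV2A, of synaptic vesicles, had a ratio of 189 (34 to 7480). Of 10 genes of serotonin synthesis and transport, SLC18A2 (2.11 ± 0.50) and QDPR (1.10 ± 0.29) rose and GCH1 (-1.19 ± 0.14) and DDC (-0.90 ± 0.20) fell, 2 and 4 adjusted over the list alone (camera, adjusted p = 0.388). Of 3 peptide hormone genes, TAC1 rose and NTS (-5.79 ± 0.85) and SCT (-2.0 ± 0.53) fell, likewise adjusted over the list alone (camera, adjusted p = 0.452). Of 12 enteroendocrine transcription factors 2 rose and 7 fell, 2 and 8 adjusted over the list alone (camera, adjusted p = 0.0101, and adjusted p = 0.257 with an estimated correlation). Among those that fell were PAX4 (-5.46 ± 0.79), NEUROD1 (-1.82 ± 0.26), INSM1 (-1.66 ± 0.25) and PAX6 (-4.24 ± 0.76). The ratios of GRIA2 and SV2A rest on single CM libraries, with log2 fold changes of 11.93 without CM replicate 6 (9.094 with it) and 10.12 without CM replicate 7 (7.276).

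Ion channels went both ways, with KCNMA1 (4.88 ± 0.49) and KCNH6 (1.24 ± 0.20) among 5 that rose and the sodium channel gene SCN3A (-2.25 ± 0.24) among 5 that fell of 13, likewise adjusted over the list alone. Camera pointed upward (adjusted p = 0.569), with a median of -0.03 and a mean of 0.67. Cell cycle inhibitors CDKN2B (-3.78 ± 0.50), CDKN2A (-2.26 ± 0.41), CDKN1C (-2.82 ± 0.54) and CDKN1A (-2.7 ± 0.53) fell and 1 rose of 8, likewise adjusted over the list alone. The inhibitors had camera adjusted p = 0.0343, and adjusted p = 0.257 with an estimated correlation. In the growth factor list 3 rose, FGFR1 (4.25 ± 0.53) among them, and 8 fell of 13, with ERBB2 (-3.17 ± 0.43) and AREG (-4.01 ± 0.64), likewise adjusted over the list alone. Growth factor genes had camera adjusted p = 0.0123, and adjusted p = 0.175 with an estimated correlation.

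Several lists fell with almost no member rising, with the same counts when adjusted over the list alone. Hypoxia genes fell in 11 of 14 (P4HA1 -2.33 ± 0.24, VEGFA -1.80 ± 0.19; camera, adjusted p = 2.2e-05). Epithelial junction and keratin genes fell in 14 of 17 (E-cadherin gene CDH1 -1.31 ± 0.19, CDH17 -1.17 ± 0.18; camera, adjusted p = 1.28e-05). Cholesterol synthesis fell in 11 of 16 (INSIG1 -1.90 ± 0.24, STARD4 -2.60 ± 0.37; camera, adjusted p = 2.2e-05). MHC class I antigen presentation fell in 12 of 15 (PSMB8 -1.06 ± 0.22, TAP1 -1.12 ± 0.26, B2M -0.69 ± 0.19; camera, adjusted p = 0.00112). With an estimated correlation the adjusted p = 0.0975, 0.0975, 0.112 and 0.268 in that order. Markers of other epithelial types fell in the same cells, 6 of 6 goblet (MUC2 -5.24 ± 0.79, adjusted p = 0.000769) and 3 of 3 Paneth markers (DEFA6 -4.67 ± 0.61, adjusted p = 0.0111). So did 9 of 13 enterocyte markers (SI -3.23 ± 0.52, adjusted p = 0.000212) and 15 of 20 brush border genes, with 1 up (ENPEP -3.55 ± 0.42, adjusted p = 2.2e-05). The corresponding adjusted p = 0.257, 0.257, 0.268 and 0.257 with an estimated correlation. Immediate early and dissociation stress genes fell in 14 and rose in 2 of 23 (IER2 -2.48 ± 0.38, SOCS3 5.39 ± 0.87). Camera gave adjusted p = 0.00305 for them, and adjusted p = 0.343 with an estimated correlation. In all, 22 of 36 lists passed, 0 with an estimated correlation.

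Different clusters held the class in these groups. Clusters 15, 16, 23, 33 and 34 held 5020 of the 5298 PTM cells (94.8%), 10 PM cells and 0 of 687 CM cells, and cluster 17 held most CM and PM cells. The changes above thus compare these clusters mostly with cluster 17. A difference between kinds of neuroendocrine-like cell was not told apart from a change within a kind. PTM replicate 2 gave 97.6% of cluster 34 (44.54% predicted doublets before filtering) and PTM replicate 15 77.6% of cluster 23. With the set as a term 2408 genes changed.

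**Figure D3:**
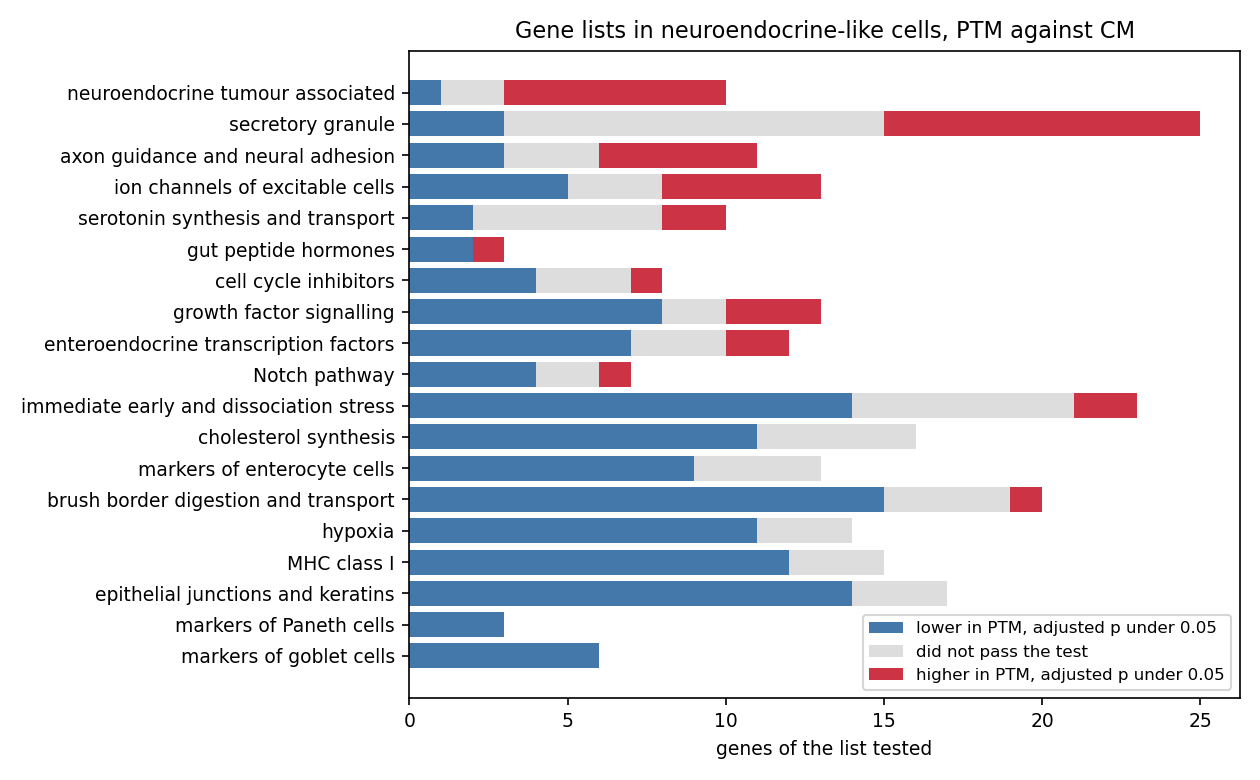
Number of tested genes (x axis) that rose, fell or did not pass the test in PTM against CM in neuroendocrine-like cells, for 19 gene lists (y axis), as stacked bars. In the hypoxia list 11 of 14 genes fell and 0 rose, while 7 of 10 genes associated with neuroendocrine tumours rose.

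Against PM, the neuroendocrine-like cells of PTM differed at 4793 genes, of which 2540 rose and 2253 fell. TAC1 rose by 4.65 ± 1.18 (SE, adjusted p = 0.00147) and SSTR2 by 1.25 ± 0.24 (adjusted p = 7.94e-05), both above the PM median in 14 of 14 samples. Most of the PM level of TAC1 comes from PM replicate 9 (755.2 CPM). Without it the log2 fold change was 8.548 (adjusted p = 1.17e-06), and with the set as a term 9.215 (adjusted p = 6.31e-06). CHGB rose by 0.75 ± 0.24 (adjusted p = 0.00932; 13 of 14) and CDKN1B by 0.45 ± 0.18 (adjusted p = 0.0403; 12 of 14). The call of CDKN1B was lost without PM replicates 1, 2, 4, 5 or 6 or PTM replicates 1, 7, 13 or 15 (adjusted p = 0.0507 to 0.0807), and with PM replicates 5 and 6 summed. CHGA fell by 1.10 (-1.10 ± 0.19, adjusted p = 1.81e-05), and TPH1 did not pass the test (-0.16 ± 0.22, adjusted p = 0.559). TMEM59L, with 0 counts in 7 PM samples, was at least 59.1-fold higher in PTM. DCX, the neuronal doublecortin gene, had a ratio of 196 (95% counting interval 54.3 to 1620), and MMP3, a matrix metalloproteinase gene, 246 (44.1 to 9710). The ratio was for TCEAL6 255 (45.8 to 10100), OLFML3 226 (40.6 to 8940), NAP1L3 186 (33.4 to 7350) and PRICKLE2 159 (28.5 to 6260). RESP18 rose by 6.92 ± 0.75, and the near-identical MBD3L2 and MBD3L2B by 7.62 ± 0.87 and 7.31 ± 0.67. In PM, all counts of DCX, TCEAL6, OLFML3, NAP1L3, PRICKLE2, MBD3L2 and MBD3L2B lie in PM replicate 9 and all of MMP3 in PM replicate 6. Without that library PM has 0 counts, and the log2 fold changes rose to 10.03 for DCX (7.086 with it), 9.652 for TCEAL6 (7.544), 9.828 for OLFML3 (7.722), 8.996 for NAP1L3 (6.884), 8.963 for PRICKLE2 (6.851), 11.82 for MBD3L2, 11.18 for MBD3L2B and 9.856 for MMP3 (7.763). RESP18, with counts in PM replicates 5 and 9, was 8.624 without PM replicate 9. SLITRK2 (-6.59 ± 0.72), ZBBX, HAPLN1 (-5.18 ± 0.83), CPXM2, the amino acid transporter gene SLC38A5 (-4.89 ± 0.64), ABCA4, STOM, PPP1R14A, LRTM1 (-4.69 ± 0.58) and PAX4 (-4.61 ± 0.80) fell the most.

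The tumour-associated list rose in 8 and fell in 1 of 10 genes against PM (GRIA2 6.51 ± 0.67, CDH6 3.61 ± 0.43, PNMA2 2.87 ± 0.30, RET 2.56 ± 0.32), and likewise adjusted over the list alone. Without PM replicate 9 GRIA2 was 11.93. It had camera adjusted p = 0.00275, and adjusted p = 0.391 with an estimated correlation. Granule genes rose in 12 and fell in 5 of 25, 12 and 6 adjusted over the list alone (SV2A 4.67 ± 0.44, SYT1 3.93 ± 0.50, RAB3B 1.74 ± 0.23, SNAP25 -0.96 ± 0.13; camera, adjusted p = 0.0767). Peptide hormone genes NTS (-4.38 ± 0.83) and SCT (-2.59 ± 0.55) fell beside the increase of TAC1, likewise adjusted over the list alone (camera, adjusted p = 0.41). Of 12 enteroendocrine transcription factors 2 rose and 8 fell, likewise adjusted over the list alone (INSM1 -1.46 ± 0.25, NEUROD1 -1.52 ± 0.27, RFX6 -1.08 ± 0.20). They had camera adjusted p = 0.0228, and adjusted p = 0.391 with an estimated correlation. Hypoxia genes fell in 11 of 14, likewise adjusted over the list alone (HK2 -4.50 ± 0.71; adjusted p = 0.00275, and adjusted p = 0.391 with an estimated correlation). Junction and keratin genes fell in 14 and rose in 1 of 17, with 2 rising adjusted over the list alone (KRT8 -1.30 ± 0.20, KRT19 -2.33 ± 0.36). Camera gave adjusted p = 3.22e-05, and adjusted p = 0.262 with an estimated correlation. Nuclear genes of oxidative phosphorylation fell in 24 of 42, likewise adjusted over the list alone (COX4I1 -1.51 ± 0.23, COX5A -1.64 ± 0.31; adjusted p = 0.000119, and adjusted p = 0.473 with an estimated correlation). Ribosomal protein genes fell in 23 of 42, 29 adjusted over the list alone (RPS19 -1.13 ± 0.21, RPLP0 -0.76 ± 0.14; adjusted p = 5.5e-05, and adjusted p = 0.473 with an estimated correlation). MHC class I genes fell in 9 of 15, 10 adjusted over the list alone (adjusted p = 0.013, and adjusted p = 0.425 with an estimated correlation). Beside these, 3 of 3 Paneth (DEFA6 -4.33 ± 0.62; adjusted p = 0.0153) and 7 of 13 enterocyte markers fell (SI -2.86 ± 0.51; adjusted p = 0.00339), likewise adjusted over the list alone, with adjusted p = 0.391 and 0.425 with an estimated correlation. The same clusters as above held the PTM and PM cells. In all, 16 of 36 lists passed, 0 with an estimated correlation.

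Mean expression of whole autosomes was compared in neuroendocrine-like cells because gains and losses of chromosomes are common in tumours, loss of chromosome 18 above all in those of the small intestine. PTM against CM, 12 of 22 autosomes were shifted, 7 higher and 5 lower (exact permutation, 14 against 8 samples). Chromosome 14 was higher by 0.212 in mean log2 expression (adjusted p = 0.000138, exact permutation) and chromosome 8 by 0.179 (adjusted p = 6.9e-05, exact permutation), both in 14 of 14 samples by the CM median. Chromosome 22 was lower (-0.221, adjusted p = 0.000757, exact permutation), as were chromosomes 9 (-0.186), 17 (-0.181), 15 (-0.179) and 6 (-0.117). Chromosome 18, with 138 genes, did not pass (-0.058, adjusted p = 0.503, exact permutation), nor did it against PM (-0.014, adjusted p = 0.876, exact permutation), where 17 autosomes were shifted, 9 higher and 8 lower. PM and CM differed at 0 autosomes by this test (6 at an unadjusted p under 0.05; 8 passed with genes of at least 50 CPM). In progenitor-like cells, taken as a control, 2, 1 and 0 autosomes were shifted in PM against CM, PTM against CM and PTM against PM. These scores follow the expression of the genes on a chromosome and its copy number alike. Within sets 1 and 2, 14 autosomes were shifted in PTM against PM (exact permutation, 210 splits). PTM against CM has 24 splits there, too few for 1 autosome to pass alone, and its largest shift was 0.211.

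**Figure D4:**
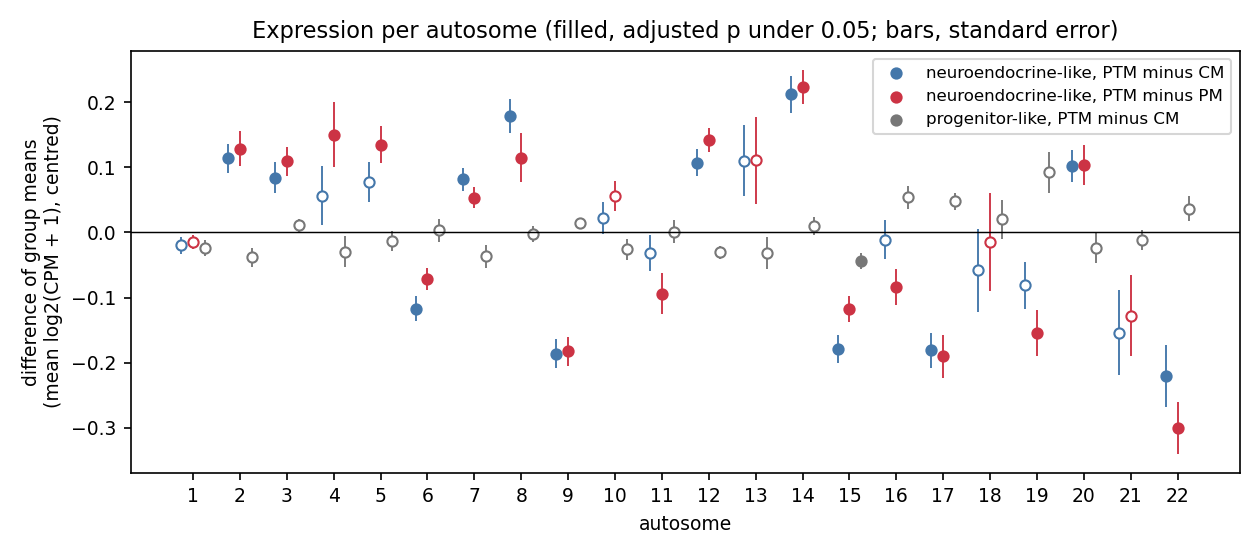
Difference of group means in the expression score of each autosome (log2, y axis; chromosome, x axis) for PTM against CM and PTM against PM in neuroendocrine-like cells and for PTM against CM in progenitor-like cells, with its standard error; filled points passed the exact permutation test. In neuroendocrine-like cells chromosome 14 was 0.212 higher and chromosome 22 was lower (-0.221) in PTM than in CM, and in progenitor-like cells 1 autosome passed.

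In progenitor-like cells, PM differed from CM at 227 of 11883 genes, 159 up and 68 down (n = 7 and 9). RBP2, the retinol-binding protein gene of the small intestinal epithelium (chromosome 3, 139452884 to 139480747), rose to 682 ± 651 CPM from 37.3 ± 14.6, a log2 fold change of 4.18 ± 0.61 (SE, adjusted p = 4.7e-05), in 7 of 7 samples. TM4SF4 (4.16 ± 0.52), PIK3C2G and SCUBE2 rose too. LEFTY1, an inhibitor of Nodal signalling (chromosome 1, 225886282 to 225911382), fell to 0.4931 ± 0.549 CPM from 34.9 ± 16.4 (-5.74 ± 0.77, adjusted p = 1.8e-05). It fell with NUPR1 (-5.66 ± 0.73), CD24 (-3.02 ± 0.46), IFI27 (-3.02 ± 0.48), CEACAM5 (-3.70 ± 0.77) and SH3KBP1 (-1.67 ± 0.26), with 9 of 9 CM samples above the PM median for each.

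Metallothionein and iron genes rose in 7 of 15, likewise adjusted over the list alone (camera, adjusted p = 1.41e-08), with MT1H (1.91 ± 0.31), MT1M (1.98 ± 0.40), MT2A (0.82 ± 0.17) and MT1X (0.90 ± 0.19), and MT1A rose as well (2.96 ± 0.43). Genes of xenobiotic metabolism rose in 3 of 24, 7 adjusted over the list alone (camera, adjusted p = 6.77e-05), with the drug exporter gene ABCG2 (1.67 ± 0.28) and with SULT2A1 (2.86 ± 0.56). Both held with an estimated correlation (adjusted p = 0.0206 and 0.032). Lipid absorption rose in 5 of 24, and 8 up and 1 down adjusted over the list alone (the cholesterol transporter gene NPC1L1 6.24 ± 0.86, MTTP, which loads lipoproteins, 1.66 ± 0.30, TM6SF2 1.52 ± 0.22; adjusted p = 1.09e-05, and adjusted p = 0.188 with an estimated correlation). Brush border genes rose in 5 of 28, likewise adjusted over the list alone (AMN 1.04 ± 0.15; adjusted p = 0.0014, and adjusted p = 0.321 with an estimated correlation). Genes of inflamed epithelium fell in 2 of 19, 8 adjusted over the list alone (CEACAM5; adjusted p = 6.77e-05, and adjusted p = 0.0596 with an estimated correlation). Enterocyte markers moved with them, 2 of 16 up and 3 adjusted over the list alone (RBP2, MTTP; adjusted p = 0.023, and adjusted p = 0.618 with an estimated correlation). Clusters 6, 10 and 14 held the class in all groups, cluster 6 most in CM (2625 of 4127 cells) and PM (885 of 1662), and cluster 10 most in PTM (1027 of 2038). With the set as a term the count was 273, with PM replicates 5 and 6 summed 113, with close pairs summed 74, and without PM replicate 5 or 6 it was 114 or 107.

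PTM progenitor-like cells differed from those of CM at 1270 genes, 815 up and 455 down (n = 15 and 9). RBP2 rose to 1066 ± 778 CPM (4.81 ± 0.59, SE, adjusted p = 8.07e-06; 15 of 15 samples). TM4SF4 rose by 3.13 ± 0.49, PLCG2 by 3.84 ± 0.82 and PIK3C2G by 3.75 ± 0.60. LEFTY1 (-4.54 ± 0.60), NUPR1 (-4.53 ± 0.57), HOXA9 (-3.19 ± 0.69; chromosome 7, 27162435 to 27175180), HOXA7, HOXA5, HOXA10, NOX1 (-2.45 ± 0.64), C10orf99, RARRES1 (-2.0 ± 0.29) and ITM2C fell, with 9 of 9 CM samples above the PTM median for each. Without PTM replicate 1 HOXA9 was -5.628, HOXA10 -5.278 (-2.809 with it), HOXA7 -4.554 (-3.02), HOXA5 -4.293 (-2.882) and NOX1 -3.626. Of 18 stem cell genes 6 fell, 7 adjusted over the list alone. Among them were LGR5, the marker of crypt base stem cells (-1.36 ± 0.27), ASCL2 (-0.92 ± 0.21), RGMB (-0.87 ± 0.19) and CDCA7 (-0.54 ± 0.13; camera, adjusted p = 2.2e-05, and adjusted p = 0.404 with an estimated correlation). The call was lost for ASCL2 with a 15% mitochondrial limit (adjusted p = 0.0541) and with the set as a term (adjusted p = 0.0663), for RGMB with a 50% limit (adjusted p = 0.0668) and for CDCA7 without doubtful libraries (adjusted p = 0.0687). Cluster 10, of lower depth, held 1027 of 2038 PTM cells but 195 of 4127 CM cells of this class. Its cells had a median of 7057 UMIs, against 17168 in cluster 6, and a median mitochondrial share of 24.89% before filtering, against 9.86%. The list of mitochondrially encoded genes pointed upward in PTM (camera, adjusted p = 0.00921, and adjusted p = 0.652 with an estimated correlation). With the mitochondrial share as a covariate LGR5 was lower by 1.349 in log2 (adjusted p = 0.00183). Of 13 Wnt targets 4 fell, likewise adjusted over the list alone (APCDD1 -2.69 ± 0.51; adjusted p = 0.0268, and adjusted p = 0.651 with an estimated correlation).

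Xenobiotic genes rose in 10 of 24, 13 adjusted over the list alone (ABCG2 1.89 ± 0.26; adjusted p = 4.63e-05, and adjusted p = 0.0262 with an estimated correlation). Lipid absorption rose in 7 of 24, 9 up and 1 down adjusted over the list alone (NPC1L1 6.34 ± 0.83; adjusted p = 0.00232, and adjusted p = 0.499 with an estimated correlation). Metallothionein and iron genes rose in 8 with 1 down of 15, 8 and 3 adjusted over the list alone (MT1X 0.81 ± 0.16; adjusted p = 0.00178, and adjusted p = 0.404 with an estimated correlation). Genes of other types moved in the same cells. Granule genes CHGB (3.66 ± 0.70), PCSK1N (2.75 ± 0.55) and CHGA (2.73 ± 0.65) were among 4 that rose and 1 fell of 9, 5 and 2 adjusted over the list alone (camera, adjusted p = 0.292). TPH1 (3.65 ± 0.71) was among 3 serotonin genes of 10 that rose, likewise adjusted over the list alone (camera, adjusted p = 0.687). Paneth markers fell in 3 of 7, 1 up and 4 down adjusted over the list alone (adjusted p = 0.0244, and adjusted p = 0.651 with an estimated correlation). Of 16 enterocyte markers 3 rose and 1 fell, 4 and 1 adjusted over the list alone (SLC5A1 0.79 ± 0.17; camera, adjusted p = 0.136). Without PTM replicate 13 CHGB was 2.819 and TPH1 2.952. The count was 538 with the set as a term, 787 without the doubtful libraries and 756 with a 15% mitochondrial limit.

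Between PTM and PM, progenitor-like cells differed at 14 genes, 10 up and 4 down. IFI27 rose to 60.7 ± 38.5 CPM (n = 15) from 13.4 ± 9.92 (n = 7), by 2.20 ± 0.46 (adjusted p = 0.0316; 15 of 15 samples). NTS, which encodes neurotensin (chromosome 12, 85874295 to 85882992), fell to 10.58 ± 10.04 from 174 ± 275 CPM (-4.14 ± 0.72, adjusted p = 0.0161). Free RNA of other enteroendocrine-like cells was not tested as its source. PRSS2, a trypsinogen gene of Paneth cells, fell (-2.82 ± 0.56, adjusted p = 0.0248). Paneth markers fell in 2 of 7, PRSS2 and ITLN2 (-3.23 ± 0.60), and 1 up and 6 down adjusted over the list alone (adjusted p = 6.37e-08, and adjusted p = 0.199 with an estimated correlation). The call of IFI27 was lost in 10 of 22 fits that left out 1 library (adjusted p up to 0.0983, without PM replicate 6). That of NTS was lost without PM replicate 4 (-3.546, adjusted p = 0.0567), and without PM replicate 2 NTS was -3.339. Calls were lost for PRSS2 without PM replicates 4, 5 or 6 (-2.455, -2.699 and -2.684) and for ITLN2 without PM replicates 5 or 6 (-3.076 and -2.636). The count of 14 rests on single libraries too. It was 173 without PM replicate 9, and 130, 25 and 22 without PTM replicates 1, 7 and 5. It was 9 without PM replicate 2 or PTM replicates 3 or 13, 8 without PM replicate 1 or PTM replicate 16, 3 without PM replicate 4, and 1 without PM replicate 5 or 6. It was 2 with PM replicates 5 and 6 summed, where IFI27, PRSS2 and ITLN2 lost their calls, 4 with the set as a term and 0 when PTM and PM were fitted alone (edgeR; 1031 at an unadjusted p under 0.05; 63 with DESeq2 over all groups).

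**Figure D5:**
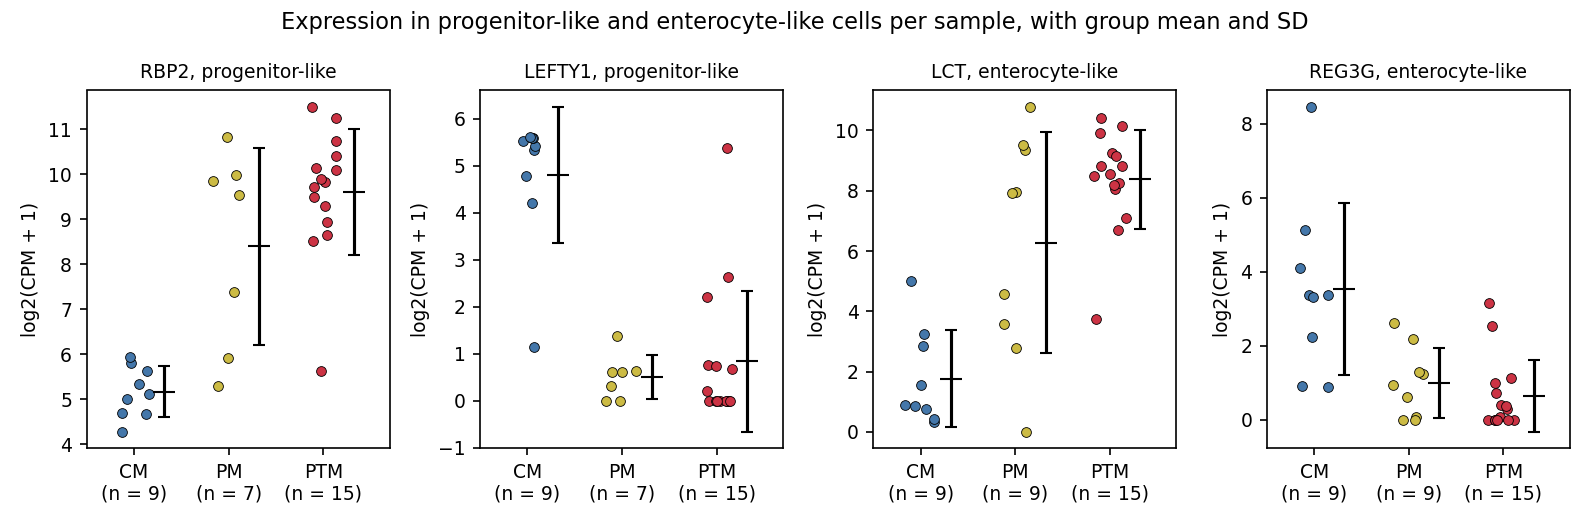
Level of RBP2 and LEFTY1 in progenitor-like cells (CM n = 9, PM n = 7, PTM n = 15) and of LCT and REG3G in enterocyte-like cells (n = 9, 9 and 15) as log2(CPM + 1) on the y axis; each point is a sample, and bars give the mean and SD. Means of RBP2 and LCT rose from 37.3 to 682 CPM and from 5.63 to 409 CPM.

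In enterocyte-like cells, PM differed from CM at 302 of 11540 genes, 187 up and 115 down (n = 9 and 9). LCT, the lactase gene (chromosome 2, 135787840 to 135837180), rose to 409 ± 580 CPM from 5.63 ± 9.98, by 6.35 ± 1.04 (SE, adjusted p = 0.000335; 8 of 9 samples). SIGLEC15 (4.45 ± 0.55), the sorbitol dehydrogenase gene SORD (4.14 ± 0.68), ANXA13 (2.92 ± 0.47), SPHK1 and TM4SF4 rose in 9 of 9 samples. RGN, ENPP7, an intestinal sphingomyelinase gene (3.61 ± 0.82), and SDR16C5 rose in 7 of 9. The antimicrobial lectin gene REG3G (chromosome 2, 79025686 to 79028505) fell to 1.43 ± 1.76 from 48.4 ± 114 CPM (-5.21 ± 1.08, adjusted p = 0.00437). So did LCN2, an iron-sequestering antimicrobial gene (chromosome 9, 128149071 to 128153455; -4.95 ± 1.00), PI3, IFI27 (-2.28 ± 0.42), C2CD4B and TNFSF15. CM replicate 3 held 77.9% of the cells of cluster 26, an enterocyte-like cluster led by REG1B, and much of this decrease rests on it. REG3G was at 352.3 CPM there and at most 34.14 in the other CM samples. Without CM replicate 3 REG3G was -2.926 (adjusted p = 0.0464) and LCN2 -4.026 (adjusted p = 0.0108), and PI3 lost its call (-1.57, adjusted p = 0.164). REG3G also lost its call without doubtful libraries (adjusted p = 0.0512). With the set as a term LCT (5.113, adjusted p = 0.0984), SORD (3.668, adjusted p = 0.129) and RGN (2.835, adjusted p = 0.264) did not pass.

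Of 16 genes of inflamed epithelium 5 fell and 1, PIGR (2.07 ± 0.47), rose, 9 and 1 adjusted over the list alone (adjusted p = 0.00589, and adjusted p = 0.454 with an estimated correlation). Lipid absorption rose in 3 of 25, 5 adjusted over the list alone (the fatty acid translocase gene CD36 2.65 ± 0.43, APOC2 2.56 ± 0.53, NPC1L1 3.54 ± 0.79; adjusted p = 2.04e-05, and adjusted p = 0.419 with an estimated correlation). MHC class I fell in 5 of 15, 9 adjusted over the list alone (adjusted p = 3.78e-07, and adjusted p = 0.305 with an estimated correlation). Interferon response fell in 2 of 26, likewise adjusted over the list alone (IFI27, IRF1 -0.98 ± 0.18; adjusted p = 2.09e-06, and adjusted p = 0.419 with an estimated correlation). Cholesterol synthesis fell in 3 of 19, 7 adjusted over the list alone (adjusted p = 3.78e-07, and adjusted p = 0.419 with an estimated correlation). Lists of stress and quality fell with them, each with 0 genes past. Camera gave adjusted p = 6.72e-06 for immediate early and dissociation stress, 0.00147 for heat shock and 0.0234 for mitochondrially encoded genes. Adjusted over the list alone 4 of 21, 6 of 12 and 0 of 13 were lower. With an estimated correlation these 3 had adjusted p = 0.429, 0.434 and 0.673. PM replicates 7 and 8 had low mitochondrial shares (1.14% and 0.199%, others 11.6% to 18.2%). In all, 15 of 34 lists passed, 4 up and 11 down, 0 with an estimated correlation. Different clusters held the class, 0, 1, 7, 24 and 26 most CM cells (8539 of 19359 in cluster 0, which held 1 PM cell), and 3, 4, 5, 8 and 12 most PM cells. PIGR lost its call without PM replicate 9 (1.453, adjusted p = 0.053). The count was 179 with the set as a term, 123 with close pairs summed and 181 without PM replicate 4.

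PTM enterocyte-like cells differed from those of CM at 1643 genes, 873 up and 770 down (n = 15 and 9). LCT rose to 494 ± 387 CPM (6.60 ± 1.03, SE, adjusted p = 3.82e-05; 15 of 15 samples). GATA4, a transcription factor gene of the upper small intestine (chromosome 8, 11676959 to 11760002), rose to 23.54 ± 14.03 from 0.672 ± 0.796 CPM (5.44 ± 0.80, adjusted p = 1.75e-05; 14 of 15). GIMD1 (7.24 ± 0.82), AQP10, RGN, SIGLEC15 (4.58 ± 0.53), NPC1L1 (4.40 ± 0.78), ENPP7, SORD and SDR16C5 rose in at least 14 of 15 samples. REG3G (-5.48 ± 0.87), CLCA4, REG3A (-3.92 ± 0.59), LCN2 (-3.47 ± 0.73), and PI3 fell. So did the Paneth cell defensin genes DEFA6 (-3.53 ± 0.62; chromosome 8, 6924693 to 6926076) and DEFA5 (-2.96 ± 0.59). Without CM replicate 3, PI3 lost its call (-1.102, adjusted p = 0.116), and REG3G was -3.278, REG3A -2.984 and LCN2 -2.54. Paneth markers fell in 6 of 6, likewise adjusted over the list alone (adjusted p = 2.05e-05, and adjusted p = 0.479 with an estimated correlation). Goblet markers fell in 3 of 8 (MUC2 -1.72 ± 0.37, CLCA1 -1.24 ± 0.23; adjusted p = 0.021, and adjusted p = 0.582 with an estimated correlation), likewise adjusted over the list alone, beside the lower shares of both classes in PTM.

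Nuclear genes of oxidative phosphorylation rose in 26 of 42, 38 adjusted over the list alone (UQCR11 0.91 ± 0.18, ATP5MC1 1.12 ± 0.23; adjusted p = 3.89e-18, and adjusted p = 0.479 with an estimated correlation). Ribosomal protein genes rose in 9 of 42, 14 adjusted over the list alone (adjusted p = 6.62e-09, and adjusted p = 0.724 with an estimated correlation). Lipid absorption rose in 5 of 25, likewise adjusted over the list alone (CD36 2.7 ± 0.41, APOC2 2.99 ± 0.50; adjusted p = 0.000248, and adjusted p = 0.688 with an estimated correlation). Of 12 genes of bile acid handling 3 rose, GATA4 among them, and NR1H4, the bile acid receptor gene (-0.93 ± 0.24), and SLC10A2, the ileal bile acid transporter gene (-1.92 ± 0.56), fell, likewise adjusted over the list alone (camera, adjusted p = 0.624). Of brush border genes, LCT was among 3 that rose and SLC6A19 (-0.90 ± 0.24) among 5 that fell of 30, 4 and 6 adjusted over the list alone. Here camera pointed downward (adjusted p = 0.579), with a median of -0.17 and a mean of 0.17. Granule genes CHGB (2.72 ± 0.61), PCSK1N (2.73 ± 0.81) and CHGA (1.51 ± 0.50) were among 4 that rose with 1 down of 10, likewise adjusted over the list alone (camera, adjusted p = 0.477). Of 5 peptide hormone genes SCT (2.02 ± 0.27) and TAC1 (2.43 ± 0.69) rose and PYY (-3.57 ± 0.69) and NTS (-1.88 ± 0.56) fell, likewise adjusted over the list alone (camera, adjusted p = 0.73). Mean CHGA in enterocyte-like cells, of which it is no marker, was 12.1 ± 7.67 CPM in CM (n = 9), 13.96 ± 16.5 in PM (n = 9) and 32.9 ± 42.2 in PTM (n = 15). TPH1 was 1.91 ± 1.24, 1.07 ± 1.27 and 7.63 ± 15.6 CPM. PTM replicate 13 was far above the rest, and without it TPH1 in PTM was 3.667 ± 2.867 CPM and CHGA 22.63 ± 14.49 (n = 14). Without PM replicate 2, CHGA in PM was 9.302 CPM and TPH1 0.6866. Without PTM replicate 13 the log2 fold change of CHGB was 1.571 (adjusted p = 0.0114), and that of CHGA was 0.9158 and no longer passed (adjusted p = 0.149). The call for CHGA was also lost without PTM replicate 5 (adjusted p = 0.054) and without CM replicates 1, 2, 4, 5, 6 or 9 (adjusted p = 0.0596 to 0.0731). PCSK1N lost its call without PTM replicate 4 (1.941, adjusted p = 0.0656), and NTS without CM replicates 3 or 8 (-1.593 and -1.589, adjusted p = 0.0589 and 0.0587). TAC1 was 3.554 without CM replicate 3. With the set as a term CHGA, CHGB and TAC1 did not pass (adjusted p = 0.219, 0.0516 and 0.267). In all, 7 of 34 lists passed, 5 up and 2 down, 0 with an estimated correlation. Clusters 3, 5, 13, 8 and 4 held most PTM cells, and cluster 0 held 5. The count was 1147 with the set as a term, 988 with close pairs summed and 1053 without the doubtful libraries.

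PTM and PM enterocyte-like cells differed at 4 genes, 1 up and 3 down. DEFA6 (-3.40 ± 0.62, adjusted p = 0.0119), PRSS2 (-2.95 ± 0.52, adjusted p = 0.0107) and DEFA5 (-2.93 ± 0.59, adjusted p = 0.0466) fell, all of them Paneth cell genes. Without PM replicate 6 DEFA6 (-3.047) and PRSS2 (-2.681) lost their calls (adjusted p = 0.0738 for both), and DEFA5 lost its call in 16 of 24 fits that left out 1 library (adjusted p up to 0.111, without PM replicate 6). Paneth markers as a list fell in 3 of 6, 5 adjusted over the list alone (adjusted p = 1.09e-08, and adjusted p = 0.227 with an estimated correlation). Goblet markers pointed downward, with 0 of 8 past and 3 down adjusted over the list alone (adjusted p = 0.000121, and adjusted p = 0.279 with an estimated correlation). Lists upward by camera with 0 genes past included ribosomal protein genes and nuclear genes of oxidative phosphorylation (adjusted p = 1.01e-13 for both). Others were immediate early and dissociation stress (adjusted p = 2.06e-09), ER stress (adjusted p = 1.66e-05) and mitochondrially encoded genes (adjusted p = 0.000157). Adjusted over the list alone 0 of 42, 5 of 42, 1 of 21, 0 of 16 and 0 of 13 rose. With an estimated correlation these 5 had adjusted p = 0.464, 0.371, 0.371, 0.345 and 0.598. PM replicates 7 and 8 had low mitochondrial shares, as above. In all, 12 of 34 lists passed, 10 up and 2 down, 0 with an estimated correlation. The number was 133 without PM replicate 9, 43 without PTM replicate 1, 8 without PM replicate 4 or 8, 7 without PM replicate 7 and 0 without PM replicate 6. With PM replicates 5 and 6 summed it was 1, and DEFA6, PRSS2 and DEFA5 lost their calls. With the set as a term it was 0 (edgeR; 1105 at an unadjusted p under 0.05), against 79 with DESeq2 over all samples.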

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

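The tests of the sequencing set, of the position of the sampled piece and of the other splits of the samples were chosen after the results were seen. An outlying sample is one whose gap to the nearest other sample of its group exceeds Dixon's 95% critical value. Chance gives this in about 1 in 20 groups of normal values, which CPM need not be. It was met in 33 of 254 groups of values (13%), 230 of them of named genes. PTM, with over 10 samples, was not examined.

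In enterocyte-like cells, transcripts of CHGA, CHGB, TPH1 and TAC1 were higher in PTM than in CM (edgeR), while against PM 0 of the 4 passed (adjusted p = 0.502, 0.101, 0.0839 and 0.0839). CHGA was in 17.8% of cells of PTM against 6.02% in CM and 6.38% in PM. The PTM means rest in part on PTM replicate 13: without it CHGA no longer passed against CM (adjusted p = 0.149), and mean CHGB fell from 13.27 to 6.409 CPM. The 1% of cells with the most UMIs of these 4 genes held a median of 13.7% of them over PTM samples (range 5.1% to 62.5%). The share was 60.99%, 62.5% and 43.93% in PTM replicates 4, 12 and 16. Predicted doublets were removed first, which can lower it, so droplets with 1 cell of each type stay open. Free RNA of the neuroendocrine-like cells of the same library stays open as a candidate source: over 15 PTM samples the level in enterocyte-like cells rose with the share of UMIs in neuroendocrine-like cells (Spearman rho 0.721, p = 0.00321; Pearson r 0.653, p = 0.00655). Without the 2 samples farthest from the median, r was 0.584 (p = 0.033) and rho 0.643 (p = 0.021; n = 13), and without PTM replicate 13 rho was 0.679 (p = 0.0092; n = 14). Expression of these genes by enterocyte-like cells themselves was not tested and stays open. Nor was free RNA tested for NTS, MUC2, DEFA6 or SI in neuroendocrine-like cells.

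Progenitor- and enterocyte-like cells of PM and PTM differed from those of CM. With the set as a term 126 of the 227 genes of PM against CM passed again in progenitor-like cells (273 in all), and 72 of the 302 in enterocyte-like cells (179 in all). For PTM against CM it was 302 of 1270 (538 in all) and 596 of 1643 (1147 in all). The sequencing set as the whole cause is argued against by the genes that passed again. For the others it stays open, as that fit has fewer samples. A single inflamed control library as the whole cause is argued against in progenitor-like cells, where 251 genes passed between PM and CM without CM replicate 3. The position of the sampled piece along the intestine stays open as a candidate explanation: the HOX genes, whose expression is ordered along the gut, were lower in PM than in CM in at least 85.7% of those tested in each class. A difference between patients and controls in the mucosa itself, which the groups name, was not tested apart from position and stays open as well.

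Of the PM samples, PM replicate 9 held 10 neuroendocrine-like cells in clusters otherwise held by PTM, with a median of 4897 UMIs. Its neuroendocrine-like cells were outlying and highest in PM for TAC1 (755.2 CPM), PEG3 (196.5), RGS5 (138.7), PAK3 and TCEAL2 (57.8 each), GLRA3 and UCHL1 (38.53 each), MBD3L2 (19.27) and MBD3L2B (15.41). DCX (7.706), NAP1L3, OLFML3, PRICKLE2 and TCEAL6 (3.853 each) were too, but other PM samples held 0, so any count is outlying. Reads swapped between libraries sequenced together are argued against, since of these 10 cells 0 had a barcode that any PTM library holds. Neither a mislabelled or mixed sample nor a biological explanation was tested.

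Other outlying samples in neuroendocrine-like cells were PM replicates 6 for MMP3 (1.68 CPM, others 0), 5 for CASD1 (1.733, lowest) and 3 for CREB3L1 (0, lowest). So were CM replicates 4 for HOXB6 (26.77, lowest) and 3 for SMIM31 (5.224, lowest). In progenitor-like cells they were PM replicate 9 for PLCG2 (1763 CPM, highest) and PM replicate 6 for SH3KBP1 (3.725, lowest). Also lowest were CM replicates 1 for HOXA7 (18.62), 4 for NOX1 (0.7983) and NUPR1 (1.083), and 9 for LEFTY1 (1.205). In enterocyte-like cells, CM replicate 3 was highest for PI3 (174 CPM), CXCL2 (157.7), SORD (9.841), AQP10 (4.026) and TPH1 (5.088), CM replicate 9 was highest for GIMD1 (1.208), and PM replicate 8 was lowest for DEFA5 (0). The share of BEST4-like cells was highest in CM replicate 9 (3.491%).

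Cell types that the comparisons do not use were seen mostly in PTM although the sort was for EpCAM. PTM held 1284 T and NK cells, against 42 in CM and 14 in PM, of which PTM replicate 16 gave 60.2% of the whole cluster. It held 399 other immune cells (CM 10, PM 0), 293 fibroblasts (CM 1, PM 0) and 218 endothelial cells (CM 0, PM 0), with PTM replicate 16 giving 66.3% and 65.0% of the first 2 clusters and PTM replicate 15 44.04% of the last.

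In other splits of the samples, 100 per comparison with the real one, chance was excluded for the counts in neuroendocrine-like cells of 46 (highest other split 19), 4365 (1170) and 4793 (1255), for 227 (51) and 1270 (381) in progenitor-like and for 302 (85) and 1643 (390) in enterocyte-like cells, each reached by 1 of 100 splits. These splits take the libraries as independent and ignore the sequencing sets and the close pairs. The count of 46 was 6 to 10 with pairs summed or the set as a term, all under the highest other split. For it chance is made unlikely only with the libraries taken as independent. Between PTM and PM the count of 14 in progenitor-like cells was reached by 6 of 100 splits (highest other 3107). That of 4 in enterocyte-like cells was reached by 7 of 100 (highest other 173), so chance stays open for both. Why some splits call several times the real count was not tested.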

How the results depend on the processing

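The fits with the pair kept apart, 2 pairs summed (PM replicates 5 and 6 as well), close pairs summed, swapped copies removed, the sequencing set as a term and without doubtful libraries, and those leaving out each library for shares and for transcripts of neuroendocrine genes in enterocyte-like cells, were chosen after seeing the data. No paired analysis was possible, as the labels tie no library to a donor. The cause was not tested for any change below, except that summed pairs, the sets, doubtful libraries left out and 30 cells leave fewer samples.

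Counts past the threshold ranged over the alternatives from 6 to 218 (PM against CM, 46 in the main analysis), 2408 to 6135 (PTM against CM, 4365) and 4286 to 6877 (PTM against PM, 4793) in neuroendocrine-like cells, from 74 to 371 (227), 538 to 1658 (1270) and 0 to 63 (14) in progenitor-like cells, and from 123 to 412 (302), 988 to 1965 (1643) and 0 to 79 (4) in enterocyte-like cells.

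For PM against CM in neuroendocrine-like cells the count was 90 with DESeq2, 27 with 30 cells, 27 with a 15% mitochondrial limit, 218 with 2 groups fitted, 10 with 2 pairs summed, 6 with close pairs summed and 9 with the set as a term. For PTM against CM it was 2408 with the set as a term. In progenitor-like cells it was 350 with DESeq2, 371 with 2 groups, 113 with 2 pairs and 74 with close pairs for PM against CM, and 756 with 15%, 749 with close pairs, 538 with the set and 787 without doubtful libraries for PTM against CM. For PTM against PM it was 63 with DESeq2, 35 with no filter, 7 with 30 cells, 9 with 15%, 8 with 50%, 9 at resolution 2, 0 with 2 groups (edgeR; 1031 at an unadjusted p under 0.05), 25 with the mitochondrial covariate, 22 with the pair kept apart, 2 with 2 pairs, 1 with close pairs, 4 with the set and 5 without doubtful libraries. In enterocyte-like cells it was 200 with 15%, 177 with 2 groups, 123 with close pairs and 179 with the set for PM against CM, and 988 with close pairs and 1053 without doubtful libraries for PTM against CM. For PTM against PM it was 79 with DESeq2, 13 with no filter, 2 with 15%, 9 with 50%, 7 with the mitochondrial covariate, 15 with the pair kept apart, 1 with 2 pairs, 2 with close pairs, 7 with swapped copies removed, and by edgeR 0 with the set (1105 at an unadjusted p under 0.05) and 0 without doubtful libraries (728).

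The difference of the neuroendocrine-like share between PTM and CM was 22.09 points with 15% (adjusted p = 0.0629), 22.09 with close pairs (0.0557) and 15.48 within sets (0.1), by exact permutation. Between PTM and PM it was 17.98 with 15% (adjusted p = 0.0778), 14.57 with 50% (0.073), 20.06 with close pairs (0.0557), 11.96 within sets (0.168) and 19.06 without doubtful libraries (0.0919), by exact permutation. Differences that did not pass the test changed sign: the progenitor-like share of PTM against PM within sets (-0.8395), and the enterocyte-like share of PM against CM with 15% (2.339), close pairs (4.555) and within sets (1.963), of PTM against CM with 15% (4.043), 50% (0.2674), close pairs (2.354), within sets (18.86) and without doubtful libraries (1.639), and of PTM against PM at resolution 2 (-0.09555) and with close pairs (-2.201).

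In neuroendocrine-like cells, 8 autosomes were shifted between PM and CM with genes of at least 50 CPM, against 0 by exact permutation in the main analysis (6 at an unadjusted p under 0.05), and 0 within sets between PTM and CM (4 at an unadjusted p under 0.05), where 24 splits are few. Of 318 gene list tests 105 passed in the main analysis, 106 with RLE, 104 with 30 cells and 3 with an estimated correlation.

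Named genes reversed in CHGB for PTM against CM in neuroendocrine-like cells with the set as a term (-0.09554), CHGA for PM against CM there with no filter (0.01336), FABP6 for PTM against CM in progenitor-like cells at resolution 2 (0.03838), MTRNR2L6 there with the set as a term (-0.02159), and TMPRSS15 at resolution 2 (-0.1091) and LYPD8 with the set as a term (0.07162) for PTM against CM in enterocyte-like cells. With no filter the median log2 fold change of all genes moved to 0.385 for PTM against CM and 0.314 for PTM against PM in neuroendocrine-like cells. Among the named genes, 119 of 387 lost their call with the set as a term, 59 of 391 with close pairs summed, 41 of 391 with 2 pairs summed and 60 of 390 without doubtful libraries.

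Leaving out 1 library gave 10 (PM replicate 6) to 54 (PM replicate 1) for PM against CM, 3983 to 4487 for PTM against CM and 4363 to 4975 for PTM against PM in neuroendocrine-like cells. It gave 107 (PM replicate 6) to 251 (CM replicate 3), 914 to 1680 and 1 (PM replicate 5) to 173 (PM replicate 9) in progenitor-like cells, and 181 (PM replicate 4) to 365 (CM replicate 9), 1301 to 1777 and 0 (PM replicate 6) to 133 (PM replicate 9) in enterocyte-like cells. The neuroendocrine-like share differed by 17.77 (without PTM replicate 15) to 22.57 (PTM replicate 1) points from CM and by 15.12 to 19.93 from PM without the same libraries. The call against PM was lost in 6 of 32 fits. The enterocyte-like share ranged from -8.783 (CM replicate 4) to 0.4447 (PM replicate 3), -7.7 (CM replicate 4) to 0.7656 (CM replicate 7) and -3.001 (PM replicate 3) to 5.412 (PM replicate 8). Between PM and CM in neuroendocrine-like cells TAC1 ranged from -4.326 (PM replicate 9) to 2.114 (CM replicate 2) and CHGA from -0.1271 (PM replicate 1) to 0.0545 (PM replicate 9). In enterocyte-like cells the mean in CPM ranged for CHGB in PTM from 6.409 (PTM replicate 13) to 14.19 (PTM replicate 7), TPH1 in PTM from 3.667 (PTM replicate 13) to 8.17 (PTM replicate 12), CHGA in PM from 9.302 (PM replicate 2) to 15.7 (PM replicate 7), TPH1 in PM from 0.6866 (PM replicate 2) to 1.199 (PM replicate 3) and TAC1 in CM from 0.5087 (CM replicate 3) to 1.12 (CM replicate 9).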

Other observations

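The tests of clusters below were run on groups of cells found in these data. TTR and LCN15 were named, and HOX genes counted, after the values were seen. Neuroendocrine-like cells fell into clusters of unlike make-up. Cluster 17, held by all 3 groups, had LCN15, a lipocalin gene, at 12880 ± 8166 CPM (SD, n = 20 samples), the hormone gene SCT, which encodes secretin, at 5570 ± 2338 and TAC1 at 7.455 ± 13.4. Cluster 40, also held by all 3 groups but with 61, 62 and 19 cells of CM, PM and PTM, had LCN15 at 22.5 ± 35.02 CPM (n = 5), SCT at 323 ± 219, the serotonergic transcription factor gene FEV at 2329 ± 326, OR51E1, an olfactory receptor gene, at 481 ± 100 and TAC1 at 55.5 ± 88.3. Cluster 16, the largest of those held by PTM, had TTR, the transthyretin gene, at 15020 ± 5690 CPM (n = 9), TAC1 at 3832 ± 1599, OR51E1 at 137 ± 34.3, FEV at 811 ± 230, SCT at 273 ± 134 and LCN15 at 2.15 ± 3.7. TPH1 was at 4897 ± 1644, 6982 ± 2280 and 4444 ± 1330 CPM in clusters 17, 40 and 16. The other enteroendocrine-like cells of cluster 20 had neurotensin (NTS) at 171400 ± 59790 CPM, SST at 37960 ± 28460 and PYY at 24390 ± 15910 (n = 22). Mean log2(CPM + 1) of genes associated with neuroendocrine tumours was 5.77 ± 0.294 in cluster 16, 3.84 ± 0.279 in cluster 40 and 2.86 ± 0.391 in cluster 17, and of secretory granule genes 8.56 ± 0.119, 7.09 ± 0.151 and 7.20 ± 0.230.

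HOX genes, which pattern the body axis, were lower in progenitor-like cells of PM than of CM in 16 of 17 tested (5 past the threshold, median log2 fold change -1.46) and in PTM in 16 of 17 (10 past, median -1.41), and 1 rose in each. In enterocyte-like cells they were lower in 12 of 14 in PM (5 past, median -1.83) and in 12 of 14 in PTM (10 past, median -1.65), and 1 rose in each. Between PTM and PM 8 of 17 and 8 of 14 were lower, and 0 passed in edgeR (medians 0.251 and -0.0904).

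A hypothesis was that all neuroendocrine-like cells of tumour mucosa, and not those of the PTM clusters alone, differ from PM. In clusters 17 and 40 alone, with 251 cells of 6 PTM samples and 6018 genes tested, 0 genes changed between PTM and PM in edgeR (216 at an unadjusted p under 0.05). The clusters were drawn from expression itself, so PTM cells that differ were placed in other clusters, and this count decides nothing: the hypothesis stays open.

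Another hypothesis was that the PTM clusters resemble cluster 40, a small cluster held by all 3 groups. Among clusters 17, 20 and 40 of CM and PM, cluster 40 correlated best with the mean PTM cluster profile in 14 of 14 samples. Mean r over 6370 genes was 0.716 ± 0.0423 (SD), against 0.639 ± 0.0438 for cluster 17 and 0.627 ± 0.0553 for cluster 20. The samples share these references and are not independent, so no p-value is given. Of these clusters, 40 was the nearest in expression, and a correlation of expression shows no descent.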
